A study of Homo sapiens with 22 samples.

How the data were processed

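Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase cuts and tags open DNA, in primary human regulatory T cells (Tregs, sorted as CD4+CD25+CD127-/low) and in conventional T cells (Tconv) from 4 donors. The cells were stimulated with 25 µl/ml of an anti-CD3/CD2/CD28 activator on days 0, 9 and 18 and harvested on day 25. All cultures held 300 IU/ml IL-2. Tregs received IL-2 alone, or IL-2 with 20 ng/ml IL-1B, 25 ng/ml IL-6, 20 ng/ml IL-23 or all 3 cytokines, and Tconv in IL-2 alone served as the reference. The 22 libraries fall into 6 groups. IL-2 Treg, IL-1B Treg, 3-cytokine Treg and Tconv have 4 replicates each, and IL-6 Treg and IL-23 Treg have 3 each. A replicate is a donor, coded 1 to 4. IL-6 Treg lacks replicate 4 and IL-23 Treg lacks replicate 3. The labels name the donor as the batch of each library.

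Per the submitters' processing notes, reads were trimmed with cutadapt 3.5 and aligned to hg38 with Bowtie2 2.4.5, filtered and de-duplicated with SAMtools 1.13 and Picard, and peaks were called with MACS2 2.2.9.1, with bedtools 2.30.0 for the intervals. The deposited count table holds raw counts, the read pairs (fragments) of each library in each consensus peak, made by featureCounts 2.0.3 in a single run per the file headers, with no normalisation. Each consensus peak is 501 bp wide. The deposited consensus peak list gives, for each of 104749 peaks, a -log10 q value, which equals that of the strongest MACS2 peak behind it as checked against the values. The 22 deposited peak lists, called per library by the authors, give the fold enrichment of each peak over background as a ratio, its -log10 p and its -log10 q. The threshold of the peak calls is not stated. All 22 columns of the count table matched a library of the labels.

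Peaks on chromosome Y and within 10 kb of XIST were left out, 165 in all, which left 104584. The table holds no mitochondrial or alternate contigs. Each peak was assigned to the nearest of 19980 protein-coding genes of the RefSeq table (GRCh38.p14), by the distance to the gene body, up to 100 kb, which gave 97460 peaks (93.19%) a gene, 59779 of them inside the gene body. The planned assignment was by distance to the transcription start site (TSS), but the gene table holds no strand. Peaks within 1 kb of a gene end therefore stood for promoter peaks, and the strand of the 10 genes named in advance was taken from general knowledge. Exons and introns are not told apart. An assigned gene is a neighbour and not a measured target.

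The depth per library, as fragments in consensus peaks, was 8744386 to 17844752, with a median of 28 fragments per peak and library. Differential accessibility was tested with edgeR 4.0.16 under R 4.3.3 (TMM scaling with factors of 0.936433 to 1.05575, filterByExpr by group, glmQLFit with robust estimation, glmQLFTest). All 22 libraries entered 1 fit with a term per group and a block for the donor, which left 13 residual degrees of freedom. The filter removed 7190 peaks and left 97394 to test. The common biological coefficient of variation was 0.119236. Tests were two-sided, p was adjusted by Benjamini-Hochberg within each of 13 comparisons, and the threshold was an adjusted p of 0.05. Every adjusted p of a single peak comes from edgeR unless another test is named. Log2 fold changes of the main fit are followed by an approximate standard error (SE) except in captions and in means over peaks. This SE is the absolute log2 fold change divided by the square root of the F statistic of glmQLFTest, and not a direct output of the fit. Levels are CPM, fragments in a peak scaled to a common library size, with TMM scaling, as mean ± SD. Same-donor libraries were checked for shared structure. After removal of the group means, the correlation of log2 CPM averaged 0.311 over 50 same-donor pairs (range 0.162 to 0.486) and -0.103 over 151 other pairs.

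Fixed before the data were examined were the comparisons, the tests, the alternatives unless named otherwise, 15 gene lists with 182 genes (174 with a tested peak) and the rule for named genes. The lists were Treg, type 17, type 1 and cytotoxic, type 2, follicular helper, naive and central memory, activation transcription factor, IL-6 and STAT3 response, IL-1 and NF-kB response, IL-23 receptor pathway and inhibitory receptor genes, and markers of CD8 T and NK cells, B cells, monocytes and myeloid cells, and erythroid cells and platelets as cell types the sorted cells could hold. Some genes stand in more than 1 list. For each of the 5 comparisons with IL-2 Treg the rule names the 10 largest rises and 10 largest falls among changed peaks with a mean log2 CPM at or above the median, the same direction in every donor and 1 peak per gene, then up to 4 genes per list with the smallest adjusted p, the TSS peaks of FOXP3, IKZF2, CTLA4, IL2RA, IRF4, IL23R, IL17A, TBX21, IFNG and 1 further gene that is not reported here, and the changed peaks within 250 kb of IRF4. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists of a comparison. Camera compares a list's peaks with all other peaks.

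The position of a library between the cell types was its log2 CPM difference from the IL-2 Treg library of the same donor, projected on the Tconv minus Treg axis, so that IL-2 Treg is 0 and Tconv is 1. The axis peaks and weights came from the other donors. Positions and peak numbers were compared by exact two-sided sign-flip permutation tests over donors, which cannot give less than 0.125 with 4 donors or 0.25 with 3. Correlations of effects across peaks are given beside 4 simulations in which no group differs, and beside the value with the IL-2 Treg libraries split between the effects, because effects measured against the same controls correlate without any change. On counts simulated from the data with 200 changed peaks, edgeR was tried in the 5 comparisons with IL-2 Treg. It recovered 78.79% to 89.39% of the 4-fold, 38.81% to 52.24% of the 2-fold and 13.43% to 23.88% of the 1.5-fold changes and called at most 8 unchanged peaks. With so few changed peaks the adjusted threshold is stricter than where many peaks change, so these shares apply to sparse changes. The spread of each simulated peak followed the fitted trend over peak level and not the peak's own spread. Camera called 0 of 100 unchanged lists. Those counts were drawn independently for each peak, without the correlation between real peaks, so this does not measure false calls on the real lists. Intervals cover counting and replicate error of these libraries only.

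The alternatives were RLE scaling, total counts only, quantile normalisation with limma-voom, the DESeq2 1.42.0 Wald test, no filter on low counts, only peaks at or above the median log2 CPM, no donor block, only the compared groups in the fit, a 2-fold threshold, leaving out each replicate, promoter peaks or an estimated correlation for the lists, all tested peaks as the axis, a -log10 q of at least 5 for the peak lists, and an overlap of at least 0.5 of the peak length for peaks called per library. Chosen after seeing the data were thinning all libraries to a single depth, leaving out the IL-23 library with a very high count at HBB, and leaving out the 2 libraries with counts at CD8A and CD8B. Motif tests and a GC correction, which need a genome sequence, were not run. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.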

Results

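Bulk ATAC-seq libraries were made from human Tregs, the T cells that hold immune responses in check, and from Tconv, their conventional counterparts. Both were expanded over 3 stimulations in IL-2. The Tregs of 4 donors were kept in IL-2 alone (n = 4) or with the inflammatory cytokines IL-1B (n = 4), IL-6 (n = 3), IL-23 (n = 3) or all 3 together (n = 4), and Tconv in IL-2 alone (n = 4) served as the reference. The 22 libraries held 8744386 to 17844752 fragments in consensus peaks. Tconv libraries had a mean of 16007200 fragments and IL-2 Treg libraries 12044300, higher in Tconv in 4 of 4 donors. Of 104584 peaks kept, 97394 were tested. Per the series title, the study concerns how inflammation reprogrammes Tregs and an element distal to IRF4, a transcription factor of T cell activation. The libraries used here come from unedited cells.

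The first comparison set Tconv against Tregs in IL-2 alone, which gives the distance between the cell types on which the cytokine effects can be placed. In FOXP3, the lineage factor of Tregs, the peak at X:49260493-49260993 went from 8.38 ± 1.43 CPM in Treg to 0.218 ± 0.124 in Tconv (SD, n = 4 each), a log2 fold change of -5.33 ± 0.37 (adjusted p = 2.24e-12). The largest fall by the naming rule was 31.7 kb outside CTLA4, an inhibitory receptor of Tregs, at 2:203835837-203836337 (log2 fold change -7.04 ± 0.50, adjusted p = 8.23e-11). A peak in FCRL3 fell by 5.54 ± 0.40 and a peak by TNFRSF1B, which encodes TNF receptor 2, by 3.72 ± 0.20 on the log2 scale. The largest rises by that rule include peaks at RAB27B, a regulator of granule release, at 18:54805908-54806408 (6.04 ± 0.28, adjusted p = 1.05e-15), at CRACR2A, a calcium channel regulator (5.52 ± 0.26), and in IL7R, the IL-7 receptor, whose low surface level was used to sort the Tregs, at 5:35859097-35859597 (5.26 ± 0.30, adjusted p = 3.71e-14). Each of these changes was seen in 4 of 4 donors. In all, 25961 peaks were more and 24433 less accessible in Tconv, 51.7% of those tested. The count was 29794 when only peaks at or above the median level were tested and 28379 with a 2-fold threshold.

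Gene lists separated the cell types as well. Of 292 peaks assigned to Treg genes, 178 fell and 45 rose in Tconv (181 and 47 adjusted over the list alone). Camera gave an adjusted p of 1.14e-11, and adjusted p = 0.0834 with an estimated correlation. A riser in that list was HPGD, which encodes an enzyme that inactivates prostaglandin E2 (log2 fold change 4.96 ± 0.31). Of 208 peaks of type 1 and cytotoxic genes, 128 rose and 17 fell (131 and 18 adjusted over the list alone; camera adjusted p = 2.74e-12, and adjusted p = 0.0191 with an estimated correlation). In the same comparison the CD8 T and NK cell markers had 36 rises and 12 falls of 63 peaks (40 and 13 adjusted over the list alone; camera adjusted p = 6.16e-05, and adjusted p = 0.145 with an estimated correlation). These include CRTAM (3.63 ± 0.28) up and NCAM1 (-4.23 ± 0.32) down. The type 1 and cytotoxic rises include peaks at FASLG, the ligand that triggers death of target cells (3.87 ± 0.15), and EOMES, a factor of cytotoxic differentiation (2.76 ± 0.16). Of 86 type 2 peaks, 48 rose and 16 fell (49 and 16 adjusted over the list alone; camera adjusted p = 0.000501, and adjusted p = 0.255 with an estimated correlation). They include GATA3 (2.92 ± 0.16) and IL4 (2.99 ± 0.27). Follicular helper peaks rose at 65 and fell at 15 of 132 sites (66 and 16 adjusted over the list alone; camera adjusted p = 6.16e-05, and adjusted p = 0.107 with an estimated correlation). These include a rise at TOX2 (4.51 ± 0.24) and IL21 (3.61 ± 0.22) and a fall at CXCR5 (-2.94 ± 0.17). The IL-23 receptor pathway rose at 71 and fell at 23 of 138 peaks (73 and 25 adjusted over the list alone; camera adjusted p = 6.16e-05, and adjusted p = 0.107 with an estimated correlation). It includes STAT3, the transcription factor that IL-6 and IL-23 signal through, at 17:42337383-42337883 (2.91 ± 0.10, adjusted p = 1.57e-17). Activation factors such as JUN (3.48 ± 0.23) and BATF3 (3.51 ± 0.25) belong to a list with 107 rises and 55 falls among 236 peaks (108 and 57 adjusted over the list alone). Its camera adjusted p was 0.0409, and adjusted p = 0.107 with an estimated correlation. That call was lost without replicate 1 (0.0911) and without replicate 2 (0.0504). Type 17 (63 rises and 89 falls of 208 peaks), naive and central memory (87 and 109 of 293), IL-6 and STAT3 response (32 and 61 of 150), IL-1 and NF-kB response (73 and 97 of 280) and inhibitory receptor genes (26 and 36 of 99) did not pass camera. Single peaks changed at IL1R1, the IL-1 receptor (-4.19 ± 0.23), BACH2, a repressor of effector genes (3.34 ± 0.18), and TIGIT, an inhibitory receptor (-4.14 ± 0.34).

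**Figure D1:**
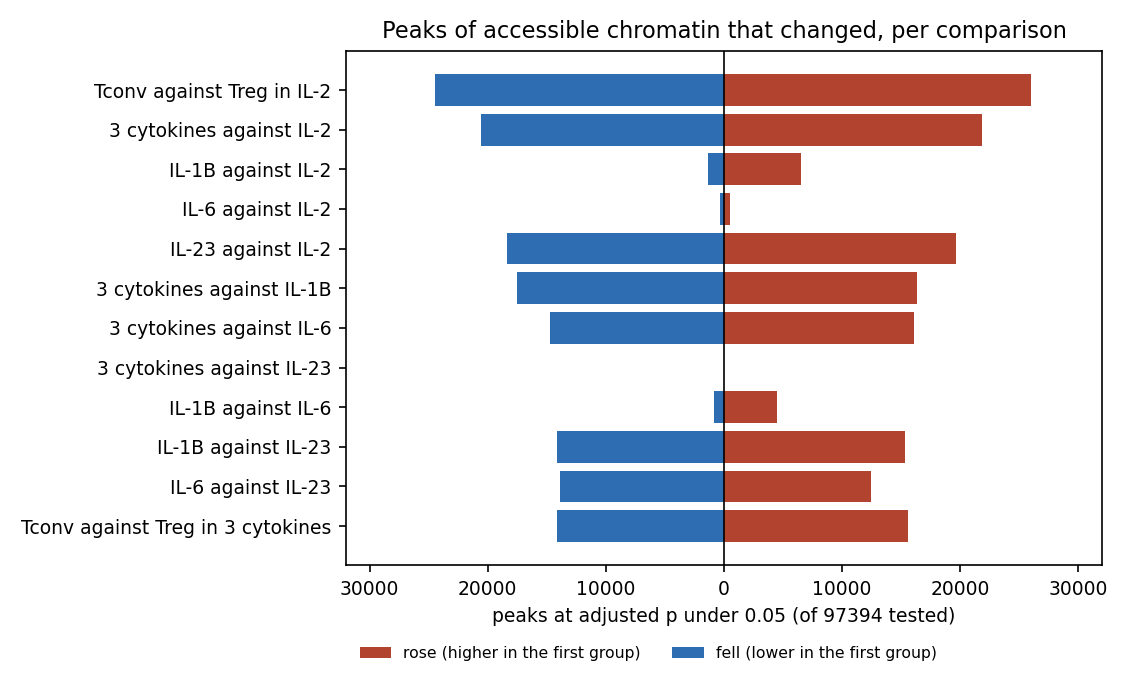
Number of peaks that rose (bars to the right) or fell (bars to the left) at an adjusted p of 0.05 in 12 comparisons, with the x axis in numbers of peaks. The 3-cytokine and IL-23 Tregs changed at 42454 and 38049 peaks against IL-2, and no peak passed between them.

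The 3-cytokine Tregs were compared with IL-2 Tregs to see what the inflammatory mixture does to Treg chromatin. The granzyme B gene GZMB, a cytotoxic effector, had the largest rise by the naming rule. Its peak 197 bp outside the gene at 14:24634137-24634637 went from 1.29 ± 0.918 to 55.6 ± 18.8 CPM (SD, n = 4 each), a log2 fold change of 5.44 ± 0.26 (adjusted p = 1.37e-12). Peaks by IFNG, the main type 1 cytokine (12:68163558-68164058, 4.85 ± 0.34, adjusted p = 7.49e-12), by IL17F, a type 17 cytokine (6:52231706-52232206, 4.79 ± 0.39, adjusted p = 1.31e-10), by CD40LG, the T cell ligand that activates B cells (4.88 ± 0.37), and in HOPX (4.75 ± 0.36) rose with it. The largest falls by the naming rule include a peak by ICOS, a costimulatory receptor (2:204023018-204023518, -4.30 ± 0.29), a peak in FOXP1, a factor that keeps T cells quiescent (-4.16 ± 0.32), and a peak by LRRC32, which encodes the surface protein that holds latent TGF-beta on Tregs (11:76637799-76638299, -3.90 ± 0.33, adjusted p = 1.93e-10). Each was seen in 4 of 4 donors. In all, 21882 peaks rose and 20572 fell, 43.6% of those tested. The count was 25456 with only peaks at or above the median level and 22111 with a 2-fold threshold.

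At the promoters named in advance, the FOXP3 TSS peak (X:49263694-49264194) fell from 3.69 ± 0.395 to 0.710 ± 0.391 CPM in the 3-cytokine Tregs, against 0.223 ± 0.0652 in Tconv (SD, n = 4 each). Its log2 fold change was -2.44 ± 0.35 (adjusted p = 2.40e-06). The TSS peak of IKZF2, which encodes the Treg factor Helios, fell from 55.7 ± 11.0 to 27.7 ± 8.33 CPM (-1.03 ± 0.18, adjusted p = 9.90e-05). The IFNG TSS peak rose from 1.49 ± 0.733 to 28.5 ± 8.50 CPM (4.25 ± 0.25, adjusted p = 1.21e-12), above the 6.66 ± 2.90 CPM of Tconv. The CTLA4 TSS peak fell by 0.43 ± 0.15 on the log2 scale (adjusted p = 0.0187). The TSS peak of TBX21, the lineage factor of type 1 cells, stood at 39.6 ± 5.07 CPM in IL-2 and 43.3 ± 5.27 CPM in the 3-cytokine Tregs and passed the test in none of the 5 comparisons with IL-2 Treg. The peak nearest the IL23R TSS, 4.40 kb from it, stood at 1.60 ± 0.718 CPM in IL-2 and 1.59 ± 0.537 CPM in the 3-cytokine Tregs (adjusted p = 1.00) and passed in Tconv alone (5.23 ± 1.42 CPM, log2 fold change 1.71 ± 0.24). The IL17A TSS peak stood at 0.716 ± 0.409 CPM in IL-2, 0.467 ± 0.176 CPM in the 3-cytokine and 1.79 ± 1.56 CPM in the IL-1B Tregs and passed in none of the 5. The IL2RA TSS peak passed in Tconv alone (log2 fold change -0.27 ± 0.09, adjusted p = 0.00982).

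**Figure D2:**
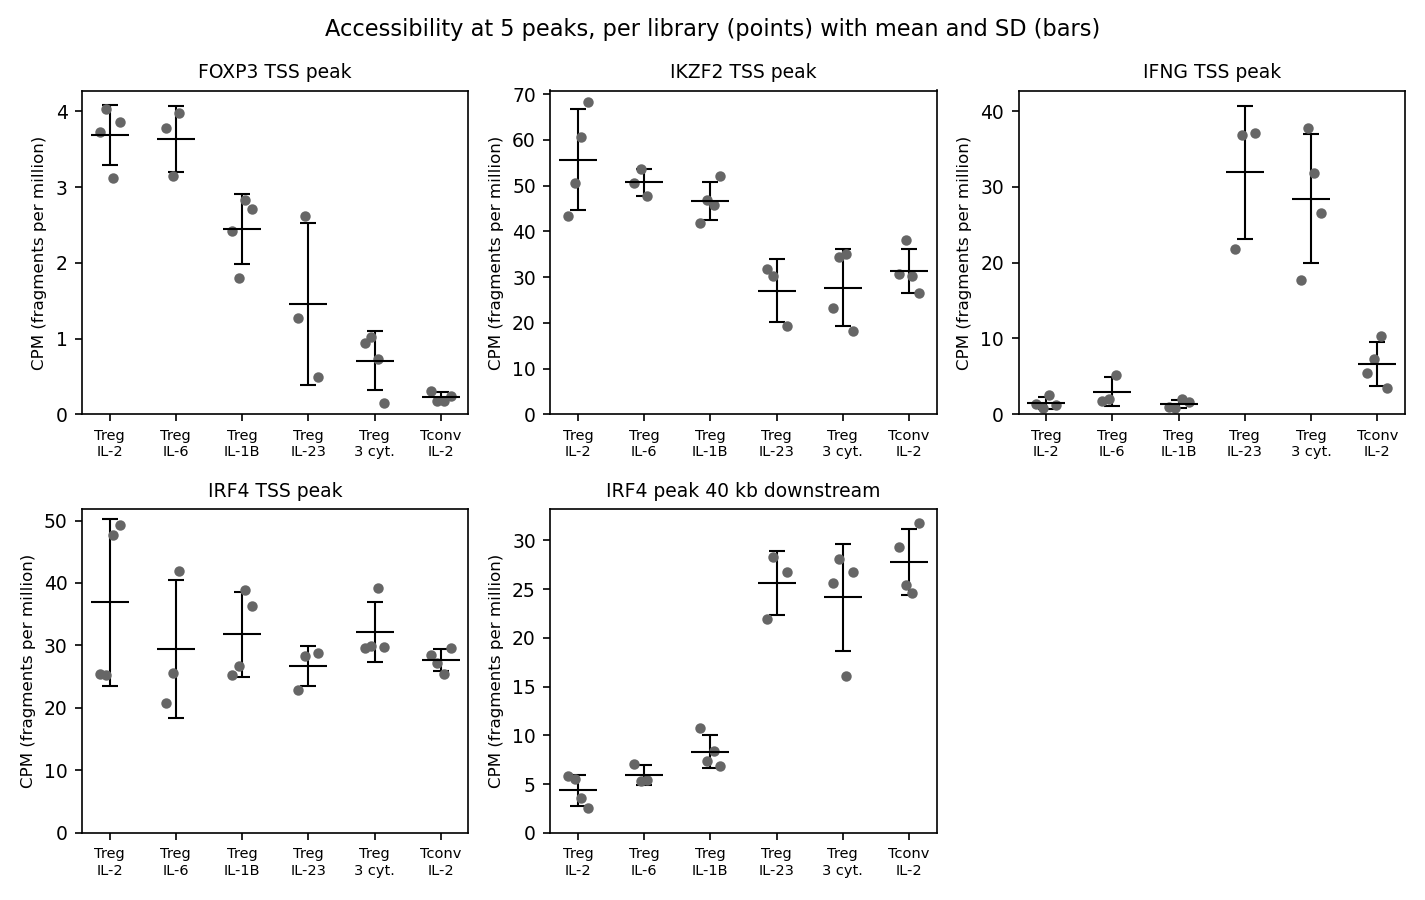
CPM of single libraries (points) with group mean and SD (bars) at 4 TSS peaks and at the IRF4 distal peak for the 6 groups, on linear axes from 0. The FOXP3 peak has a mean of 3.69 CPM in IL-2 Treg and 0.710 in 3-cytokine Treg, and the IFNG peak 1.49 and 28.5.

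By list, 178 of 292 Treg gene peaks fell and 27 rose in the 3-cytokine Tregs (185 and 28 adjusted over the list alone; camera adjusted p = 5.24e-14, and adjusted p = 0.0470 with an estimated correlation). Among the 4 smallest p-values were falls at LRRC32 and TNFRSF1B (-2.34 ± 0.18) and rises at HPGD (3.97 ± 0.25) and IL10, an anti-inflammatory cytokine gene (1.61 ± 0.14). Type 1 and cytotoxic genes rose at 120 and fell at 15 of 208 peaks (125 and 16 adjusted over the list alone; camera adjusted p = 2.05e-16, and adjusted p = 0.00572 with an estimated correlation). They include FASLG (3.52 ± 0.15, adjusted p = 1.73e-15), IFNG and the chemokine gene CCL5 (4.07 ± 0.27). In the same comparison the CD8 T and NK cell markers rose at 38 and fell at 8 of 63 peaks (38 and 9 adjusted over the list alone; camera adjusted p = 0.000313, and adjusted p = 0.300 with an estimated correlation), for example GZMK (3.58 ± 0.31). The peaks with the highest counts in CD8A and CD8B, genes of the CD8 lineage, stood at 13.3 and 16.1 CPM in 1 of the 4 3-cytokine libraries, and were also raised in 1 IL-23 library, against at most 2.38 and 5.89 CPM in the other 20 libraries. These genes were picked after their values were seen. Without these 2 libraries 36966 peaks changed between 3-cytokine and IL-2 Tregs. Type 17 genes rose at 81 and fell at 37 of 208 peaks (83 and 41 adjusted over the list alone; camera adjusted p = 0.0143, and adjusted p = 0.465 with an estimated correlation). They include the cytokine genes IL26 (2.08 ± 0.16) and IL21 (2.68 ± 0.24) and AHR, a receptor for environmental ligands (3.26 ± 0.30). The IL-23 receptor pathway rose at 57 and fell at 19 of 138 peaks (59 and 19 adjusted over the list alone; camera adjusted p = 9.07e-05, and adjusted p = 0.174 with an estimated correlation). It includes STAT3 (2.66 ± 0.10), CSF2 (1.98 ± 0.20), IL23R (2.01 ± 0.22) and SOCS3 (2.28 ± 0.25). Follicular helper genes had 46 rises and 23 falls of 132 peaks (47 and 23 adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.465 with an estimated correlation; 0.0633 without replicate 4). Naive and central memory genes had 59 rises and 111 falls of 293 peaks (64 and 120 adjusted over the list alone; camera adjusted p = 0.0240, and adjusted p = 0.465 with an estimated correlation). There were rises at IL7R (3.31 ± 0.23), BACH2 (2.53 ± 0.19) and S1PR1 (1.72 ± 0.13). The type 2 (22 rises, 21 falls), activation factor (68 and 54), IL-6 and STAT3 response (48 and 40), IL-1 and NF-kB response (57 and 80) and inhibitory receptor (23 and 40) lists did not pass. In them EGR2, a factor induced by strong receptor signals, fell at 1 peak (-3.43 ± 0.25), IL1RAP, part of the IL-1 receptor, rose (3.11 ± 0.28), PDCD1, which encodes PD-1, rose (1.46 ± 0.16) and TIGIT fell (-2.55 ± 0.30).

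**Figure D3:**
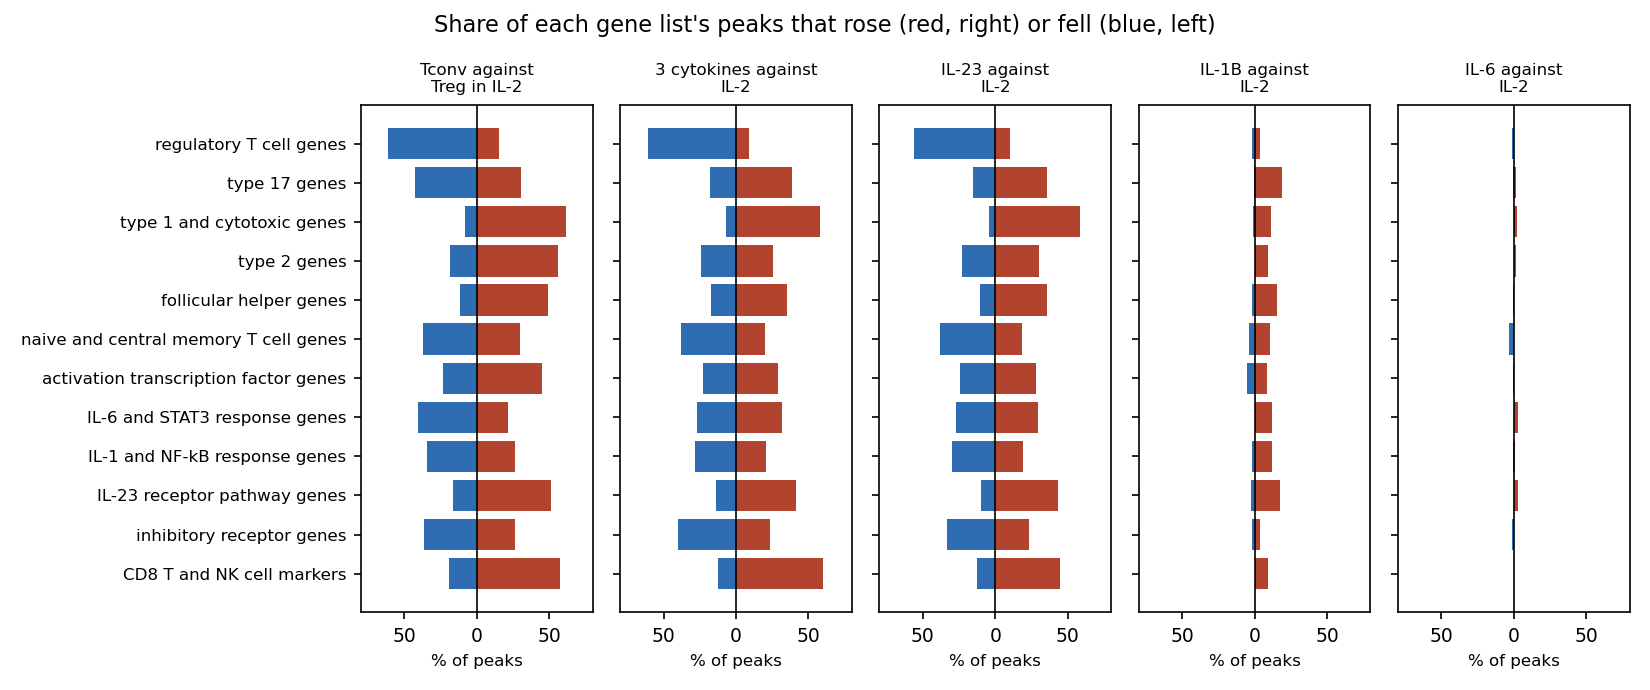
Percent of the tested peaks of 12 gene lists that rose (right) or fell (left) at an adjusted p of 0.05 in the 5 comparisons with IL-2 Treg. Type 1 and cytotoxic peaks rose at 120 of 208 sites and Treg gene peaks fell at 178 of 292 sites in the 3-cytokine Tregs.

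Much of this change ran in the direction of Tconv. Of the 21882 peaks that rose in the 3-cytokine Tregs, 15121 also rose in Tconv, where independent lists would share 5832.79, and of the 20572 that fell, 14785 also fell in Tconv, against 5160.85. The values for independent lists ignore that both comparisons share the IL-2 Treg libraries, which can raise the overlap without any change. The log2 fold changes correlated across peaks, which are not independent replicates, at r = 0.693 (covariance 0.779). Simulated groups without change that share the controls gave r = 0.523 (covariance 0.0429), and r averaged 0.614 (range 0.590 to 0.648) with the IL-2 Treg libraries split between the effects. On the axis from IL-2 Treg (0) to Tconv (1), the 3-cytokine Tregs lay at 0.595 ± 0.0466 (SD, n = 4) and were above 0 in 4 of 4 donors (exact sign-flip p = 0.13, the smallest that 4 donors allow). Tconv and 3-cytokine Tregs still differed at 29741 peaks, 15594 higher and 14147 lower in Tconv. That count was 15653 with only peaks at or above the median level and 16829 with a 2-fold threshold.

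Some changed peaks lay beyond both IL-2 Treg and Tconv. Of the peaks that rose in the 3-cytokine Tregs, 5905 (27.0%) were more accessible than in Tconv. At 1118 of these IL-2 Tregs were below Tconv, at 661 they were already above it, and at 4126 they did not differ from it. Of the peaks that fell, 3531 (17.2%) were less accessible than in Tconv, with IL-2 Tregs above Tconv at 583, below it at 481 and not different at 2467. By count, 43 of the 81 risen type 17 peaks and 31 of the 120 risen type 1 and cytotoxic peaks lay above Tconv, and the difference between the lists was not tested. Of the 178 Treg gene peaks that fell, 25 lay below Tconv. A peak in RORA, which encodes a nuclear receptor of type 17 cells (15:60540237-60540737), was at 2.48 ± 0.412 CPM in IL-2 Treg, 5.60 ± 1.83 in 3-cytokine Treg and 0.649 ± 0.298 in Tconv (SD, n = 4 each). Its log2 difference was 3.03 ± 0.28 from Tconv (adjusted p = 7.43e-09) and 1.10 ± 0.24 from IL-2 Treg. The largest such difference was at a peak in RCAN2, a calcineurin regulator, with 5.18 ± 0.28 (adjusted p = 5.52e-11), where IL-2 Tregs were already at 16.1 ± 6.61 CPM against 0.864 ± 0.790 CPM in Tconv, and the rise over IL-2 was 1.02 ± 0.19. These peaks were picked after their values were seen. They come from a list of the largest differences from Tconv among peaks above Tconv in both the 3-cytokine and the IL-23 Tregs. The list held peaks with an assigned gene and a mean level at or above the median, 1 per gene. The RCAN2 peak headed that list, and the RORA peak stood near its end.

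**Figure D4:**
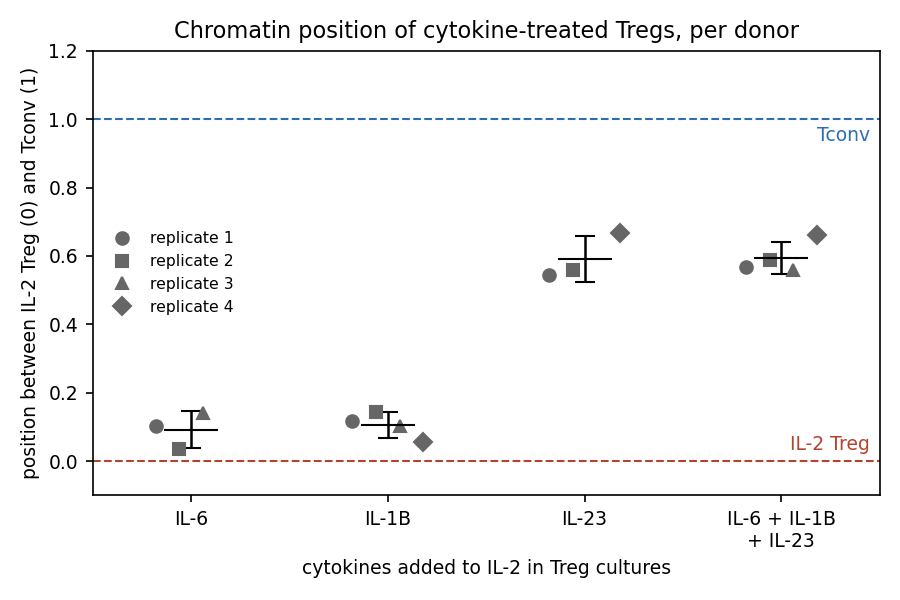
Position of each cytokine-treated Treg library (points, by donor) with group mean and SD on the axis from IL-2 Treg (0) to Tconv (1). The 3-cytokine and IL-23 groups have means of 0.595 and 0.591, and the IL-1B and IL-6 groups 0.105 and 0.0921.

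IL-23 alone was added to Tregs to ask what this cytokine, which sustains type 17 cells, does by itself. The GZMB peak at 14:24634137-24634637 rose to 44.9 ± 16.8 CPM (SD, n = 3), a log2 fold change of 5.35 ± 0.28 (adjusted p = 5.12e-12). Peaks by IFNG (5.13 ± 0.35), IL17F (4.73 ± 0.41) and IL26 (2.38 ± 0.17, adjusted p = 1.22e-11) rose. Falls include the ICOS peak (-4.22 ± 0.32), a peak by IKZF2 at 2:213157282-213157782 (-3.17 ± 0.30, adjusted p = 2.41e-09) and a peak by TNFAIP3, an inhibitor of NF-kB (-2.50 ± 0.26). Each was seen in 3 of 3 donors. At the TSS peaks, FOXP3 fell to 1.46 ± 1.07 CPM (-1.32 ± 0.33, adjusted p = 0.00220) and IKZF2 to 27.1 ± 6.81 CPM (-1.02 ± 0.19), and IFNG rose to 31.9 ± 8.81 CPM (4.61 ± 0.26, adjusted p = 1.01e-12). In all, 19647 peaks rose and 18402 fell, 39.1% of those tested. The count was 23972 with only peaks at or above the median level and 20261 with a 2-fold threshold.

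By list, IL-23 lowered 164 and raised 29 of 292 Treg gene peaks (172 and 31 adjusted over the list alone; camera adjusted p = 4.93e-12, and adjusted p = 0.0760 with an estimated correlation). It raised 122 and lowered 9 of 208 type 1 and cytotoxic peaks (125 and 10 adjusted over the list alone; camera adjusted p = 1.53e-18, and adjusted p = 0.00332 with an estimated correlation). They include FASLG (3.48 ± 0.16) and CCL5 (4.23 ± 0.28). CD8 T and NK cell markers had 28 rises and 8 falls of 63 peaks (32 and 8 adjusted over the list alone; camera adjusted p = 0.000767, and adjusted p = 0.361 with an estimated correlation). The CD8A and CD8B peaks stood at 9.96 and 11.0 CPM in 1 of the 3 IL-23 libraries, and without it and the 3-cytokine library named above 28277 peaks changed with IL-23. Type 17 genes had 74 rises and 32 falls of 208 peaks (77 and 33 adjusted over the list alone; camera adjusted p = 0.00849, and adjusted p = 0.433 with an estimated correlation). The IL-23 receptor pathway had 60 and 14 of 138 (61 and 16 adjusted over the list alone; camera adjusted p = 6.53e-05, and adjusted p = 0.161 with an estimated correlation). Follicular helper genes had 47 and 14 of 132 (47 and 16 adjusted over the list alone; camera adjusted p = 0.00849, and adjusted p = 0.370 with an estimated correlation). Naive and central memory genes had 53 rises and 112 falls of 293 peaks (57 and 119 adjusted over the list alone; camera adjusted p = 0.00849, and adjusted p = 0.370 with an estimated correlation). The type 2 (26 rises, 20 falls), activation factor (66 and 57), IL-6 and STAT3 response (44 and 41), IL-1 and NF-kB response (54 and 83) and inhibitory receptor (23 and 33) lists did not pass. Rises at the type 2 cytokine gene IL9 (3.28 ± 0.53) and at HAVCR2, which encodes TIM-3 (0.96 ± 0.12), belong to these lists.

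With IL-23 alone the Treg libraries also lay towards Tconv. Whether the Tregs themselves changed or other cells grew out in the cultures was not tested. The position of these libraries was 0.591 ± 0.0670 (SD, n = 3, above 0 in 3 of 3 donors, exact sign-flip p = 0.25, the smallest that 3 donors allow). The effect correlated with the Tconv difference at r = 0.704 across peaks (covariance 0.761), against 0.487 (0.0420) in simulations without change and 0.620 with split controls. Of its risen peaks 14230 also rose in Tconv and 4479 (22.8%) lay above Tconv, and of its fallen peaks 13686 also fell in Tconv and 2607 (14.2%) lay below.

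The 3-cytokine and IL-23 Tregs were compared directly to ask what IL-6 and IL-1B add to IL-23. The edgeR test called 0 of 97394 peaks, with a lowest adjusted p of 0.550. At an unadjusted p of 0.05 there were 3742 peaks, where chance would give 4869.7. The DESeq2 and limma-voom tests called 0 peaks as well, and 1 peak passed in edgeR without replicate 4. An approximate median 95% interval, built from the approximate SE with 4 libraries against 3, was ± 0.60 on the log2 scale. It leaves room for smaller differences at single peaks. Larger ones can be missed too, since edgeR recovered 38.81% to 52.24% of the simulated 2-fold changes in the comparisons with IL-2 Treg. The 2 effects against IL-2 shared 17500 risen and 16128 fallen peaks, where independent lists would share 4414.19 and 3886.95, and 0 peaks were called in opposite directions. The values for independent lists again ignore the shared controls. They correlated at r = 0.940 across peaks (covariance 0.840), against 0.464 (0.0421) in simulations and 0.822 with split controls. By list, the Treg genes (camera adjusted p = 0.0208, and adjusted p = 0.800 with an estimated correlation) and the type 2 genes (camera adjusted p = 0.00721, and adjusted p = 0.800 with an estimated correlation) were lower in the 3-cytokine Tregs as groups, with mean log2 differences of -0.12 in both and 0 single peaks past the threshold over all peaks or over the list alone. The positions on the axis differed by 0.0161 ± 0.0188 (SD, n = 3 donors, exact sign-flip p = 0.5).

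IL-1B alone, a cytokine that activates NF-kB, opened chromatin more often than it closed it. The IL17A region rose at 6:52157510-52158010, 28.6 kb outside the gene (log2 fold change 2.00 ± 0.21, adjusted p = 2.39e-06). A peak by IL17F rose by 1.52 ± 0.19 (adjusted p = 2.17e-05). The STAT3 peak at 17:42337383-42337883 rose by 1.42 ± 0.11 (adjusted p = 1.40e-08) and a peak by CSF2, which encodes the inflammatory growth factor GM-CSF, by 1.42 ± 0.18 (5:132098958-132099458, adjusted p = 2.36e-05). The largest rises by the naming rule include peaks in AUTS2 (3.29 ± 0.71, adjusted p = 0.00812), by ZEB2 (2.67 ± 0.60), in TCF4 (2.57 ± 0.36) and in MCOLN2 (2.47 ± 0.28, adjusted p = 1.26e-05), and the largest fall was in ST6GAL1, a sialyltransferase gene (-1.26 ± 0.24). Each was seen in 4 of 4 donors. In all, 6543 peaks rose and 1324 fell, 8.08% of those tested, so that 83.2% of the changed peaks rose. Quantile normalisation gave 5480 rises and 2612 falls, or 67.7% rising, and DESeq2 5228 and 2005, or 72.3%. The count was 2234 without the donor block, 3730 with a 2-fold threshold, 16691 with only the 2 groups in the fit, and 4328, 3496 and 2764 without replicates 1, 3 and 4.

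Among the lists, type 17 genes rose at 39 and fell at 1 of 208 peaks with IL-1B (54 and 3 adjusted over the list alone; camera adjusted p = 4.88e-05, and adjusted p = 0.381 with an estimated correlation). They include AHR (1.38 ± 0.18) and RORA (1.40 ± 0.24). The IL-23 receptor pathway rose at 24 and fell at 3 of 138 peaks (30 and 3 adjusted over the list alone; camera adjusted p = 0.00292, and adjusted p = 0.381 with an estimated correlation). Type 2 genes rose at 8 and fell at 0 of 86 peaks (8 and 1 adjusted over the list alone; camera adjusted p = 0.00501, and adjusted p = 0.503 with an estimated correlation). They include IL9 (1.60 ± 0.29), IL13 (1.59 ± 0.34) and IL5 (1.34 ± 0.33). The IL5 peak went from 0.719 ± 0.366 to 1.87 ± 0.744 CPM, a level of few fragments. Follicular helper genes rose at 20 and fell at 2 of 132 peaks (27 and 3 adjusted over the list alone; camera adjusted p = 0.00501, and adjusted p = 0.381 with an estimated correlation). They include IL21 (1.98 ± 0.36) and TOX (1.75 ± 0.27). The IL21 peak, 11.8 kb outside the gene, went from 0.401 ± 0.121 to 1.51 ± 0.323 CPM, again few fragments. IL-6 and STAT3 response genes rose at 18 and fell at 0 of 150 peaks (22 and 2 adjusted over the list alone; camera adjusted p = 0.0399, and adjusted p = 0.381 with an estimated correlation), a call lost without the donor block (0.0501) and without replicates 1 (0.0868) and 4 (0.0842). The IL-1 and NF-kB response list had 34 rises and 5 falls of 280 peaks and did not pass (camera adjusted p = 0.273). Peaks 20.6 kb outside IRAK3 (2.04 ± 0.45) and 45.3 kb outside TNIP3 (1.14 ± 0.19), feedback inhibitors of that pathway, rose. The IRAK3 peak went from 0.252 ± 0.144 to 1.09 ± 0.499 CPM, a level of few fragments. Treg genes had 11 rises and 6 falls of 292 peaks (9 and 4 adjusted over the list alone; adjusted p = 0.287), with rises at IL10 (0.93 ± 0.17), IL2RA, the high-affinity IL-2 receptor chain (0.89 ± 0.16), and ENTPD1, which encodes the ectoenzyme CD39 (2.92 ± 0.53), and a fall at TIGIT (-0.77 ± 0.25), which did not pass with DESeq2 (adjusted p = 0.0812). The ENTPD1 peak went from 0.202 ± 0.216 to 1.66 ± 0.992 CPM, also a level of few fragments. Type 1 and cytotoxic (23 rises, 2 falls), naive and central memory (31 and 11), activation factor (21 and 13) and inhibitory receptor (4 and 2) lists did not pass, though EOMES (2.02 ± 0.27) and BATF (0.73 ± 0.13) rose and KLF2, a factor of T cell recirculation, fell (-0.71 ± 0.12). The FOXP3 TSS peak was at 2.44 ± 0.463 CPM with IL-1B and did not pass (adjusted p = 0.203). The position on the axis was 0.105 ± 0.0372 (SD, n = 4, exact sign-flip p = 0.13). The correlation with the Tconv difference was 0.294 across peaks (covariance 0.169), against 0.521 (covariance 0.0428) in simulated groups without change, and 0.184 with split controls. The simulated r comes from the shared controls alone and is not a level that a real effect must exceed.

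IL-6 alone, which signals through STAT3, changed the fewest peaks. The STAT3 peak at 17:42337383-42337883 rose from 7.11 ± 1.84 (n = 4) to 16.5 ± 4.77 CPM (n = 3), a log2 fold change of 1.19 ± 0.12 (adjusted p = 7.58e-06). The GZMB peak rose by 2.24 ± 0.34 (adjusted p = 0.00236), a peak in MAF, a factor of IL-10 and type 17 cytokine expression, by 2.15 ± 0.40 (adjusted p = 0.00696), the IL17A region by 1.06 ± 0.24 (adjusted p = 0.0240) and a peak by CCL5 by 1.42 ± 0.28. Peaks in CARD19 (2.15 ± 0.28) and STON2 (2.12 ± 0.27) were among the largest rises by the naming rule. Falls include a peak by CCR8, a chemokine receptor of tissue Tregs (-1.86 ± 0.34, adjusted p = 0.00500), the FOXP1 peak (-1.75 ± 0.27), a peak by ICOS (-1.58 ± 0.29), a peak by IL1R1 (-1.55 ± 0.34), a peak in IKZF2 (-1.24 ± 0.31) and a peak by FOXO1, a factor of quiescence (-1.36 ± 0.26). Each was seen in 3 of 3 donors. In all, 534 peaks rose and 374 fell, 0.932% of those tested and 58.8% of them rising, and 11512 passed an unadjusted p of 0.05. Quantile normalisation gave 607 rises and 670 falls, 47.5% rising, and RLE 475 and 437. The count was 44 without the donor block, 503 with a 2-fold threshold, 4515 with only the 2 groups in the fit, and 335, 395, 77 and 611 without replicates 1, 2, 3 and 4.

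With IL-6, naive and central memory genes fell at 10 and rose at 0 of 293 peaks (22 and 4 adjusted over the list alone; camera adjusted p = 0.000834, and adjusted p = 0.305 with an estimated correlation). Treg genes fell at 3 and rose at 0 of 292 peaks (5 and 0 adjusted over the list alone; camera adjusted p = 0.000834, and adjusted p = 0.335 with an estimated correlation), the peaks at CCR8, LAYN (-1.04 ± 0.24) and IKZF2. Type 1 and cytotoxic genes rose at 5 and fell at 0 of 208 peaks (12 and 1 adjusted over the list alone; camera adjusted p = 0.00325, and adjusted p = 0.305 with an estimated correlation). Those named by the rule were at GZMB, CCL5, IL12RB2 (0.65 ± 0.14) and STAT4 (0.82 ± 0.17). IL-6 and STAT3 response genes rose at 4 and fell at 0 of 150 peaks (4 and 1 adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.305 with an estimated correlation). They include HIF1A (0.85 ± 0.17) and BCL3 (0.80 ± 0.19), and the list's call was lost without replicate 2 (0.174). The IL-23 receptor pathway, which shares STAT3 with that list, rose at 4 and fell at 0 of 138 peaks (5 and 0 adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.335 with an estimated correlation; 0.118 without replicate 3). Among markers of other cell types, B cell markers passed camera in the same comparison (adjusted p = 0.00325, and adjusted p = 0.305 with an estimated correlation), where 0 of 38 single peaks passed edgeR and 1 rose adjusted over the list alone. Type 17 (3 rises, 1 fall), type 2 (1 and 0), follicular helper (0 and 1), activation factor (1 and 2), IL-1 and NF-kB response (2 and 1) and inhibitory receptor (0 and 1) lists did not pass. The FOXP3 TSS peak stood at 3.63 ± 0.437 CPM (n = 3). The position on the axis was 0.0921 ± 0.0531 (SD, n = 3, exact sign-flip p = 0.25), and the correlation with the Tconv difference was 0.339 across peaks (covariance 0.172), against 0.480 (0.0435) in simulations and 0.206 with split controls.

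The cytokines were also compared with each other. IL-1B and IL-23 Tregs differed at 29439 peaks, 15298 higher and 14141 lower with IL-1B, and IL-6 and IL-23 Tregs at 26323, 12412 higher and 13911 lower with IL-6. Only 2 donors, replicates 1 and 2, gave both an IL-6 and an IL-23 library. The other libraries of these groups enter that comparison through the donor block alone. IL-1B and IL-6 Tregs differed at 5350 peaks, 4516 of them (84.4%) higher with IL-1B, or 3837 of 5596 (68.6%) after quantile normalisation. The 3-cytokine Tregs differed from IL-1B Tregs at 33786 and from IL-6 Tregs at 30828 peaks. On the axis they lay 0.490 ± 0.0780 above IL-1B Tregs (SD, 4 of 4 donors, exact sign-flip p = 0.13) and 0.480 ± 0.0685 above IL-6 Tregs (3 of 3 donors, exact sign-flip p = 0.25), and IL-23 Tregs lay 0.485 ± 0.110 above IL-1B Tregs (3 of 3 donors, exact sign-flip p = 0.25). Treg gene peaks fell at 177 and rose at 23 of 292 sites in 3-cytokine against IL-1B Tregs (188 and 24 adjusted over the list alone), and type 1 and cytotoxic peaks rose at 113 and fell at 13 of 208 (124 and 15 adjusted over the list alone). Type 17 peaks were higher at 28 and lower at 1 of 208 sites with IL-1B than with IL-6 (46 and 3 adjusted over the list alone; camera adjusted p = 3.71e-05, and adjusted p = 0.562 with an estimated correlation). The counts for 3-cytokine against IL-1B, 3-cytokine against IL-6, IL-1B against IL-6 and IL-1B against IL-23 were 20497, 20020, 3084 and 18337 with only peaks at or above the median level and 18015, 15692, 3375 and 16535 with a 2-fold threshold, which gave 13810 for IL-6 against IL-23. IL-1B against IL-6 gave 1146, 1746 and 3367 without replicates 1, 2 and 3 and 8882 with only the 2 groups in the fit, 3-cytokine against IL-6 gave 19574 and 18664 without replicates 1 and 2, and IL-1B against IL-23 gave 19360 without replicate 4. Without the donor block the counts were 867 for IL-1B against IL-6, 18853 for IL-1B against IL-23 and 17172 for IL-6 against IL-23, which was 16242, 11992 and 17325 without replicate 1, replicate 2 and the 2 libraries with CD8A and CD8B counts. Against the sum of the 3 single effects, the mixture was higher at 82 and lower at 757 peaks, and quantile normalisation gave 137 and 539. That count was 1320 with DESeq2, 23 without the donor block and 282, 34 and 134 without replicates 1, 3 and 4, and 278 without the 2 libraries with CD8A and CD8B counts.

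The IRF4 locus was read as a region because the study's title names an element there. Of 71 tested peaks within 250 kb of the gene (6:391752-411443), 25 rose and 24 fell in Tconv, 25 and 23 in 3-cytokine, 21 and 22 in IL-23, 14 and 1 in IL-1B and 1 and 0 in IL-6 Tregs. This window, and that around FOXP3, was set by distance alone, whichever gene a peak was assigned to. The 1 peak with IL-6 (6:195769-196269, 1.23 ± 0.30, adjusted p = 0.0432) did not pass with DESeq2 (adjusted p = 0.0614). Adjusted over the locus alone the counts were 25 and 25, 25 and 23, 24 and 23, 17 and 2, and 2 and 0. The smallest p of the region in Tconv, 3-cytokine and IL-23 Tregs was at the peak 6:432023-432523, 20.8 kb past the gene. It was at 4.36 ± 1.58 CPM in IL-2 Treg, 8.33 ± 1.73 with IL-1B, 5.92 ± 1.00 with IL-6, 25.7 ± 3.28 with IL-23, 24.2 ± 5.46 with the mixture and 27.8 ± 3.34 in Tconv (SD, n = 4, 4, 3, 3, 4 and 4). The log2 fold changes were 2.67 ± 0.18 in Tconv (adjusted p = 2.20e-12), 2.45 ± 0.19 with the mixture (adjusted p = 5.18e-11), 2.48 ± 0.19 with IL-23 (adjusted p = 1.41e-10) and 0.93 ± 0.20 with IL-1B (adjusted p = 0.00415), and 0.44 ± 0.23 with IL-6 did not pass (adjusted p = 0.453). A further peak at 6:467736-468236 rose by 2.99 ± 0.24 in Tconv, 1.67 ± 0.26 with the mixture, 1.92 ± 0.27 with IL-23 and 1.80 ± 0.26 with IL-1B. Inside IRF4, the peak at 6:399824-400324 fell by 1.68 ± 0.14 in Tconv and by 1.10 ± 0.14 with the mixture. The IRF4 TSS peak was at 36.9 ± 13.3 CPM in IL-2 Treg and 32.1 ± 4.76 with the mixture (-0.16 ± 0.14, adjusted p = 0.387). In Tconv it was at 27.7 ± 1.80 CPM (-0.35 ± 0.14, adjusted p = 0.0415), lower in 2 of 4 donors and higher in 2, and did not pass without replicate 3 (adjusted p = 0.207) or replicate 4 (adjusted p = 0.256). For IL-1B, 6 peaks of the region changed without the donor block and 25 with only the 2 groups in the fit. Over leaving out single replicates or IL-23 replicate 1 the count went as low as 6.

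**Figure D5:**
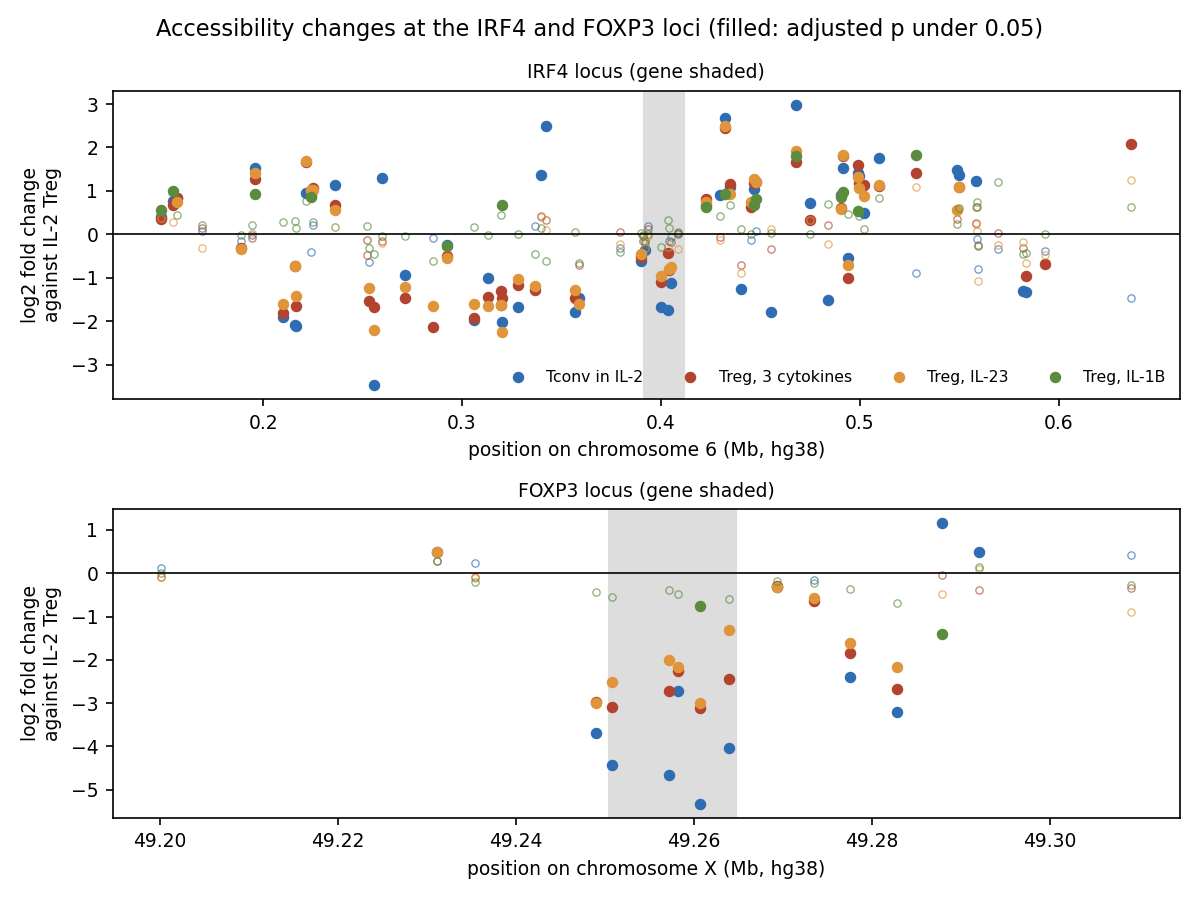
Log2 fold change of every tested peak near IRF4 (within 250 kb) and FOXP3 (within 50 kb) by position, for Tconv, 3-cytokine, IL-23 and IL-1B against IL-2 Treg, with filled points under an adjusted p of 0.05 and open points above it. The IRF4 distal peak rose by 2.67 in Tconv and 2.45 with the 3 cytokines, and the FOXP3 peak at 49260493 fell by 5.33 and 3.11.

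Of 16 tested peaks within 50 kb of FOXP3 (X:49250438-49264710), 9 fell and 3 rose in Tconv, 10 fell and 0 rose in 3-cytokine Tregs, 10 fell and 1 rose with IL-23, 2 fell with IL-1B (1 with DESeq2, total counts only or no filter on low counts) and 0 changed with IL-6 in edgeR, where 1 fell adjusted over the locus alone. A rise in Tconv did not pass with DESeq2 (log2 fold change 0.474, adjusted p = 0.110). The peak at X:49260493-49260993 fell by 3.11 ± 0.31 with the mixture, 3.01 ± 0.32 with IL-23 and 0.77 ± 0.24 with IL-1B on the log2 scale, and the peak at X:49250591-49251091 by 3.10 ± 0.27 with the mixture and 2.52 ± 0.27 with IL-23.

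Markers of other cell types were read in the same comparisons with IL-2 Treg. CD8 T and NK cell markers, given above for Tconv, 3-cytokine and IL-23 Tregs, had 6 rises and 0 falls with IL-1B and with IL-6 0 changes, and neither passed. B cell markers, which passed camera with IL-6 alone, had 11 rises and 15 falls in Tconv, 11 and 9 with the mixture, 11 and 7 with IL-23 and 0 changes with IL-1B. Monocyte and myeloid markers changed at 9, 7, 4, 2 and 0 of 24 peaks in Tconv, mixture, IL-23, IL-1B and IL-6, and erythroid and platelet markers at 4, 3, 3, 0 and 0 of 12, and neither passed in any comparison. The erythroid changes with IL-23 include HBB, the beta-globin gene, at 11:5225357-5225857. Its peak held 584 CPM in 1 IL-23 library and at most 3.28 CPM in the other 21, and its log2 fold change of 6.24 ± 1.86 (adjusted p = 0.0164) became -3.43 without that library. No gene list test past its threshold in these 5 comparisons had a median, mean and test of different sign, and 13 of the 43 others did.

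Peaks called by the authors per library numbered 46282 ± 6438 in IL-2 Treg (SD, n = 4), 50159 ± 4700.4 with IL-1B (n = 4), 46573 ± 1533 with IL-6 (n = 3), 53813 ± 1817 with IL-23 (n = 3), 49732 ± 5176 with the mixture (n = 4) and 55812 ± 1902 in Tconv (n = 4). Tconv had more than IL-2 Treg in 4 of 4 donors (mean difference 9530.75, exact sign-flip p = 0.13, the smallest that 4 donors allow). IL-23 Tregs had more in 3 of 3 donors (exact sign-flip p = 0.25), and in 2 of 3 donors (exact sign-flip p = 0.5) at a -log10 q of at least 5. Tconv libraries held the most fragments in peaks on average.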

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

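In 2 of 58 tested groups of 4 libraries, 1 library lay far from the other 3. Chance gives about 1 in 20 such groups. At the IRF4 TSS peak of the 3-cytokine Tregs the gap took 0.963 of the group's range, with 1 library at 39.3 CPM and the next at 29.9 (lowest 29.6). At the IL17A TSS peak of the 3-cytokine Tregs it took 0.911 of the range, with 1 library at 0.204 CPM and the other 3 at 0.535 to 0.567 CPM, a level of few fragments. The library at 39.3 CPM is from replicate 3, which was also the highest at this IRF4 peak with IL-1B (38.9 CPM) and IL-6 (41.9 CPM). In IL-2 Treg replicates 3 and 4 stood at 47.7 and 49.2 CPM, above replicates 1 and 2 at 25.5 and 25.2 CPM. In Tconv replicate 3 was the lowest, at 25.4 CPM. A difference between donors was not tested, nor was any explanation for the IL17A peak.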

How the results depend on the processing

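Thinning to a single depth, leaving out IL-23 replicate 1 and leaving out the 2 libraries with CD8A and CD8B counts were chosen after seeing the data. RLE scaling, total counts, quantile normalisation and no filter on low counts kept the count of changed peaks within 1.5 times in every comparison and in the IRF4 locus, and so did DESeq2 except for the sum of single effects (1320). The single peaks called in the IRF4 locus were not all the same ones. With DESeq2, the 1 with IL-6 (adjusted p = 0.0614), 3 with IL-1B and 2 with the mixture no longer passed, nor did the peaks at S100A9 (Tconv, adjusted p = 0.0810), TIGIT (IL-1B, adjusted p = 0.0812) and CSF2 (IL-6, adjusted p = 0.0582). In the FOXP3 locus with IL-1B the count of 2 became 1 with total counts, no filter and DESeq2. A peak of that locus that rose in Tconv did not pass with DESeq2 (adjusted p = 0.110). Where a setting did more, the cause was not tested, except that fewer peaks are tested at or above the median level, a 2-fold threshold calls fewer, and leaving out libraries lowers power.

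With only peaks at or above the median level the counts were 29794 (Tconv against IL-2 Treg), 25456 (3-cytokine), 23972 (IL-23), 20497 (3-cytokine against IL-1B), 20020 (against IL-6), 3084 (IL-1B against IL-6), 18337 (IL-1B against IL-23), 15653 (Tconv against 3-cytokine) and 0 in the IRF4 locus with IL-6. With a 2-fold threshold they were 28379, 22111, 3730 (IL-1B), 503 (IL-6), 20261 (IL-23), 18015, 15692, 3375, 16535, 13810 (IL-6 against IL-23) and 16829. Without the donor block they were 2234 (IL-1B), 44 (IL-6), 867, 18853, 17172, 23 for the sum of single effects, and 6 and 0 in the IRF4 locus with IL-1B and IL-6. With only the 2 groups they were 16691, 4515 and 8882 (IL-1B against IL-6), and 25 and 7 in the IRF4 locus. Thinning gave 509 for the sum and 0 in the IRF4 locus with IL-6, which had 2 without IL-23 replicate 1. Without the 2 libraries with CD8A and CD8B counts, IL-6 against IL-23 gave 17325, the sum 278 and the IRF4 locus with IL-6 0.

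Over leaving out each replicate or IL-23 replicate 1, the counts ranged from 2764 to 7977 (IL-1B), 77 to 983 (IL-6), 18664 to 31104 (3-cytokine against IL-6), 0 to 1 (against IL-23), 1146 to 5547 (IL-1B against IL-6), 19360 to 27321 (IL-1B against IL-23), 11992 to 23097 (IL-6 against IL-23), 34 to 773 for the sum, and 6 to 16 and 0 to 2 in the IRF4 locus with IL-1B and IL-6.

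Of 75 gene list tests 32 passed, 8 on peaks within 1 kb of a gene end and 4 with an estimated correlation. The correlations of effects with split controls were 0.614, 0.184, 0.206 and 0.620 for Tconv with 3-cytokine, IL-1B, IL-6 and IL-23, and 0.822 for 3-cytokine with IL-23. With a -log10 q of at least 5 the called peaks per library averaged 45259 (IL-1B), 42251.3 (IL-6), 48685.3 (IL-23) and 51845 (Tconv). The log2 fold change reversed for the HBB peak with IL-23 (-3.43 without IL-23 replicate 1, and a range of -3.77 to 8.55 over leaving out replicates). TSS peaks that did not pass also reversed, with ranges over leaving out replicates of -0.331 to 0.0282 (FOXP3 with IL-6), -0.287 to 0.0429 (IRF4 with 3 cytokines), -0.0733 to 0.00753 (TBX21 in Tconv) and -0.251 to 0.0196 (TBX21 with IL-6). TBX21 in Tconv was also 0.0168 with total counts. On promoter peaks the direction of 3 lists reversed, follicular helper with IL-1B (adjusted p = 0.417) and IL-6 and STAT3 response with IL-1B (adjusted p = 0.0906) and IL-6 (adjusted p = 0.860). Over single peaks and lists, 7969 values kept direction and side of the threshold, 635 no longer passed, 10 passed newly, 10 reversed and 6 moved, the last being shares of called peaks overlapping a consensus peak. Motif tests and a GC correction were not run. Depth limits calls at peaks of few fragments.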

Other observations

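The tests for a mixture, for CD8-lineage cells and for too few libraries, and all splits of the libraries, were chosen after the results they measure were seen, and so were thinning and leaving out the 2 libraries with CD8A and CD8B counts.

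Beside the named genes, 3592 peaks rose in the 3-cytokine and in the IL-23 Tregs against IL-2 and lay above Tconv in both. Peaks picked among them after their values were seen lie in PER3, a gene of the circadian clock, in AKAP6, which encodes an anchor of protein kinase A, and 60.1 kb from BMAL1, a further clock gene. In the 3-cytokine Tregs the log2 difference was 3.13 ± 0.33, 4.72 ± 0.40 and 3.69 ± 0.32 from Tconv and 0.72 ± 0.26, 1.15 ± 0.28 and 2.91 ± 0.31 from IL-2 Treg, so for PER3 and AKAP6 most of the difference from Tconv was already there in IL-2. No list of clock genes was tested.

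The first pattern weighed is that IL-23 and 3-cytokine Treg libraries lay towards Tconv, at a mean position of 0.591 and 0.595. A mixture of IL-2 Treg and IL-2 Tconv cells would leave every peak between the levels of those cells, and 27.0% of the peaks that rose with the 3 cytokines lay above Tconv at an adjusted p of 0.05, which argues against such a mixture as the whole source. Cells of the CD8 lineage in place of CD4 cells would lower the peaks of CD4 and ZBTB7B, the factor that sets the CD4 lineage, and their median log2 fold change with the 3 cytokines was 0.0406. The Tregs were sorted as CD4+CD25+CD127-/low, a gate meant to leave out CD8 cells and conventional T cells. The purity of the sort was not analysed here, so a share of CD8 cells stays open in the 2 of 7 libraries with counts at CD8A and CD8B. Without these libraries 36966 peaks changed with the 3 cytokines and 28277 with IL-23. A difference in library size is argued against by thinning all libraries to a single depth, with 38799 changed peaks. A change of the Tregs themselves under IL-23 and outgrowth of conventional T cells that themselves respond to the cytokines were not tested and remain open.

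The second pattern is that no peak differed between 3-cytokine and IL-23 Tregs. IL-1B against IL-23, which has the same numbers of libraries, called 29439 peaks, so these numbers suffice for large and widespread differences. That comparison cannot speak to small or sparse ones. On the simulated counts edgeR recovered 38.81% to 52.24% of the 2-fold and 13.43% to 23.88% of the 1.5-fold changes in the comparisons with IL-2 Treg. Differences of that size at single peaks therefore stay open. 2 copies of a single library would give a chi-square per degree of freedom near 1, and the lowest over the same-donor pairs was 1.66. That was also the lowest of all 231 pairs of libraries. The 3 same-donor pairs, at up to 2.0505, lay below the closest pair within a group (2.0528), which holds different donors. The test does not address separate libraries of the same culture. IL-1B may add a weaker effect on top of IL-23. Over the 6543 peaks that rose with IL-1B alone the mean log2 difference of 3-cytokine from IL-23 Tregs was 0.0481 ± 0.270 (SD, 3 donors, range -0.215 to 0.324, exact sign-flip p = 0.75, smallest possible 0.25), against 1.12 for IL-1B alone. With 2 of 3 donors above 0, this cannot be told apart from no added effect. The value of 1.12 is over peaks chosen for rising in that same comparison, which raises it. Of the 6543 peaks, 3898 had also risen with IL-23 alone, so the 2 values are not on an equal footing.

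The third pattern is that 83.2% of the peaks changed by IL-1B rose. Over 3 other scalings the lowest share was 67.7%, with quantile normalisation, which also changes the test, and with all libraries thinned to a single total, which also lowers the depth, it was 64.3%. In each case most changed peaks still rose, which argues against scaling of the libraries or a difference in library size as the whole cause. Why the share moved was not tested, and no biological explanation was tested.

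The libraries pair by donor, so the real split of the libraries of each comparison was compared with the other splits that part as many donor pairs, fitted with only those libraries. These make 8 splits with 4 donors, 4 with 3 donors and 2 for IL-6 against IL-23, too few for a share under 0.05. The real split alone (1 split) gave as many peaks as the real count in 11 comparisons, and the highest other split that parts as many pairs gave 0. Those other splits leave the difference between the real groups in the residual spread, which lowers their calls. Their 0 is therefore no support for the real counts. The real counts were 43229 (Tconv against IL-2 Treg), 32182 (3-cytokine against IL-2), 16691 (IL-1B against IL-2), 4515 (IL-6 against IL-2), 30418 (IL-23 against IL-2), 26490 (3-cytokine against IL-1B), 23859 (3-cytokine against IL-6), 8882 (IL-1B against IL-6), 23476 (IL-1B against IL-23), 27102 (IL-6 against IL-23) and 21067 (Tconv against 3-cytokine Treg). Splits that part fewer pairs mix donors with groups, and the highest of them gave 3193 for IL-1B against IL-2, 1472 for IL-6 against IL-2, 4159 for IL-1B against IL-6 and 0 for the other 8. For 3-cytokine against IL-23 the real count of 0 is the lowest possible, so that 4 of 4 splits reach it by design and decide nothing. The highest other gave 6, and 306 over splits that part fewer pairs.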
